A study of Homo sapiens with 9 samples.

How the data were processed

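The deposited series matrix holds 1 log2 value per probe set and array for 54675 probe sets on 9 Affymetrix arrays, and these log2 values had been made with RMA (background correction, quantile normalization and median polish) per the submitters' processing notes, which give no version. No raw files were used, and the values entered the analysis as deposited, with 0 sample columns left unmapped. The labels state that H69 cells were treated for 24 h with DMSO, 100 nM PIK75 or 1 mM TGX221, and that 2 ug of total RNA were labelled per array. The unit of the TGX221 dose could not be checked from the files. The treatment field of the control samples reads none, while the protocol gives DMSO, and they are treated here as the DMSO control. The replicate numbers of the groups differ in part (1, 3 and 5 for control and PIK75, 2, 3 and 5 for TGX221) and were not used as a block.

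Gene symbols came from a platform annotation table. Of the probe sets, 62 are Affymetrix controls, 41091 carry exactly 1 gene symbol (41037 of them with an Entrez identifier in the reference gene table), 1801 carry several and 11721 carry none. Each of the 19775 genes was represented by its brightest probe set with a single symbol, that is, the one with the highest mean log2 value over all 9 arrays, and 10523 genes had more than 1 such probe set. For PIK75 against control, where another probe set of a named gene moved the opposite way and passed the test, this is given with the gene. Some genes and preset list entries are not analysed here (of 1212 list entries, 1102 were matched).

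Differences between groups were tested with limma (lmFit and eBayes) on all 9 arrays with 3 group means and no covariate, so that the 3 comparisons share 1 estimate of spread (6 residual degrees of freedom and a prior of 6.155). P-values were adjusted over all genes by Benjamini and Hochberg, and a gene was called at an adjusted p below 0.05. Standard errors and 95% intervals come from the same fit. The smallest p of an exact test of 3 arrays against 3 is 0.1, so exact tests were not used for single genes. For each preset list the count adjusted over the list alone repeats the Benjamini and Hochberg step on the p-values of the members. In simulated data with known changes, the fit recovered 29 of 50 genes changed by 1.25-fold and all 50 at 1.5-fold, with 5 false calls. The simulation drew each gene independently and changed 200 of the 19775 genes. Its 5 false calls therefore do not give the error rate in the real data.

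The 42 gene lists were written from general knowledge before the values were seen and cover PI3K signalling, cell death, the cell cycle, DNA repair, metabolism, translation, stress responses, lineage markers and markers of other cell types. They were tested with camera of limma, which compares the members with all other genes, at a preset inter-gene correlation of 0.01 and with adjustment over the lists, for lists with at least 5 measured genes. Because the members of a list vary together, each called list is also given with the correlation estimated from these arrays.

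The genes named were chosen by rule: per comparison the 10 highest and 10 lowest log2 fold changes among called genes whose 3 values per group do not overlap and whose mean log2 value is at least 6 in 1 of the groups, up to 4 members with the smallest p of each list described, and a fixed set of PI3K, survival and cell cycle genes. Not every gene that the rule admits is named.

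The alternatives planned before the values were seen were other scalings (array medians, poly-A spikes), leaving out genes below the median brightness, the mean of the probe sets of a gene, every probe set on its own, a fit on only the 2 groups compared, a trended and robust spread, array weights, the replicate number as a block, a minimum of 1.5-fold, an adjusted p below 0.01, leaving out each array in turn and the estimated correlation for lists. Centring on the hybridization spikes, cyclic loess and the actin 3' minus 5' value as a covariate were chosen after seeing the data. The poly-A spikes (24 probe sets) are added to the RNA before labelling and the hybridization spikes (18 probe sets) after it. RMA makes the arrays alike in distribution, so a change common to most genes cannot be measured from these values. The overlap of both inhibitors was set against 100 simulated data sets with unchanged groups that share the controls. The work used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.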

Results

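Gene expression was measured on 9 arrays in H69 cells, a human small cell lung cancer line of neuroendocrine type that grows in suspension. The cells had been kept for 24 h with the vehicle DMSO (control), with PIK75 at 100 nM, or with TGX221 at a labelled dose of 1 mM, and each group holds 3 arrays. The labelled TGX221 dose lies far above the PIK75 dose and its unit could not be checked, so the dose behind the TGX221 comparisons is uncertain. Both compounds inhibit phosphoinositide 3-kinases (PI3K), lipid kinases that relay growth factor signals, but they differ in the isoforms they prefer, and TGX221 is known as an inhibitor of the isoform encoded by PIK3CB. The comparisons ask what each inhibitor did to the transcriptome, and whether the responses differed. Each of the 19775 genes has 1 value per array on a log2 scale. The median of the gene values lay between 8.20 and 8.23 on all 9 arrays. The interquartile range of gene values was 2.78 to 2.83 on the control arrays, 2.71 to 2.77 with TGX221 and narrower, 2.48 to 2.57, with PIK75. Control arrays correlated with each other at r = 0.9977 to 0.9983, with TGX221 arrays at 0.9956 to 0.998 and with PIK75 arrays at 0.9724 to 0.9786 (Pearson, across genes, which are not independent replicates). The arrays of a group differ in number only, so p-values measure the spread between arrays, which may be technical, and 3 arrays per group limit the precision.

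With PIK75, the lists of HIF1 targets, cholesterol synthesis and neuroendocrine markers were called lower at a preset correlation of their members. None of these calls held with an estimated correlation (adjusted p = 0.638, 0.145 and 0.163). The largest fall was in TPH1, the enzyme that starts serotonin synthesis, which was 7.12-fold lower (log2 fold change -2.83, SE 0.115, adjusted p = 2.63e-09). CALB1, a calcium-binding protein of neurons, was 5.95-fold lower (log2 -2.57), and PDK1, the kinase that restrains pyruvate dehydrogenase, was 5.91-fold lower (log2 -2.56). The largest rise was in AMDHD1, an amidohydrolase of histidine breakdown, which went from a dim mean of 5.95 to 9.81 (log2 3.86, SE 0.11, adjusted p = 3.38e-10). SLC3A2, the heavy chain of an amino acid exchanger at the cell surface, was 2.92-fold higher (log2 1.55, adjusted p = 1.48e-07).

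The other genes among the 10 largest rises were the long noncoding RNAs ZSCAN16-AS1 (log2 2.33), LINC00326 (log2 2.31) and LOC101929774 (log2 1.66). They also took in the zinc finger gene ZC3H12D (log2 2.17), the cilium gene CFAP43 (log2 1.76), the aldehyde dehydrogenase ALDH8A1 (log2 1.73), the Nodal antagonist LEFTY1 (log2 1.73) and the nucleoporin NUP58 (log2 1.46). AMDHD1, LINC00326, ZC3H12D and CFAP43 had control means under 6, where signal was not told apart from background, so their rises may be larger than measured. Further falls were in the tight junction gene CLDN11 (log2 -2.49), the ubiquitin ligase adaptor DCAF16 (log2 -2.38) and the mitophagy receptor BNIP3L (log2 -2.34). The last of the 10 largest falls were in the calmodulin-binding peptide PCP4 (log2 -2.33), the long noncoding RNA DRAIC (log2 -2.30), the neural progenitor gene MTURN (log2 -2.29) and DEPTOR, which binds and restrains mTOR (log2 -2.28). These 20 genes were picked among genes whose 3 PIK75 arrays lay on one side of the 3 control arrays, as 12793 genes (64.7%) did, where chance gives 10%. The probe sets of 1 gene did not always move together. Other probe sets of NUP58 fell (log2 -0.59 and -1.02) and the mean of its probe sets did not pass (-0.03, adjusted p = 0.729, over a range of 1.3e-24 to 0.729), 2 dimmer ones of CLDN11 rose (log2 0.30 and 0.21), and of 2 further probe sets of PDK1 one had a value of -0.12 (adjusted p = 0.197) and the other rose (log2 0.17).

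Genes of glucose use and of the response to low oxygen were lower with PIK75. Of 22 measured target genes of HIF1, the transcription factor of hypoxia, 17 fell and 2 rose, with the same counts adjusted over the list alone. Their median log2 change was -1.14 (adjusted p = 0.000167 by camera, a test of a list against all other genes, and adjusted p = 0.638 with an estimated correlation). Beside PDK1, the members with the smallest p were DDIT4, an inhibitor of mTORC1 (log2 -1.80, SE 0.148), ANKRD37 (log2 -1.21) and the mitophagy receptor BNIP3 (log2 -1.49). Glycolysis and glucose uptake had 15 of 23 members lower and 2 higher, also adjusted over the list alone (median -0.44, adjusted p = 0.000137, and adjusted p = 0.601 with an estimated correlation). Among them were PFKM (log2 -0.84), PGK1 (log2 -0.95) and ENO1 (log2 -0.83), which encode enzymes of the pathway.

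Lipid synthesis followed the same direction. In cholesterol synthesis and uptake, 15 of 19 genes fell and 1 rose, with the same counts adjusted over the list alone (median -0.70, adjusted p = 7.38e-07, and adjusted p = 0.145 with an estimated correlation). STARD4, a sterol carrier, was 4.77-fold lower (log2 -2.25, SE 0.058), SQLE, squalene epoxidase, 3.12-fold lower (log2 -1.64) and HMGCS1, an early enzyme of the pathway, 3.06-fold lower (log2 -1.61). LSS, lanosterol synthase, was 2.06-fold lower (log2 -1.04), although 2 dim probe sets of LSS rose (log2 0.20 and 0.41). All 14 genes of fatty acid synthesis passed the test, 11 lower and 3 higher, and also adjusted over the list alone (median -0.31, adjusted p = 0.00527, and adjusted p = 0.163 with an estimated correlation). They included SCD, stearoyl-CoA desaturase (log2 -1.14), and ACACA, acetyl-CoA carboxylase (log2 -0.83).

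Neuroendocrine markers, which set this tumour type apart, had 24 of 34 members lower and 5 higher with PIK75, with the same counts adjusted over the list alone (median -0.32, adjusted p = 1.31e-05, and adjusted p = 0.163 with an estimated correlation). SNAP25, a protein of vesicle release, was 2.82-fold lower (log2 -1.50, SE 0.0529), SEZ6L 2.47-fold lower (log2 -1.30), the decarboxylase DDC 2.31-fold lower (log2 -1.21) and RUNDC3A 1.67-fold lower (log2 -0.74). Of 26 markers of non-neuroendocrine small cell lung cancer, 16 rose and 4 fell, with the same counts adjusted over the list alone, but the list was not called (median 0.19, adjusted p = 0.229), and its median was -0.19 once arrays were centred on the hybridization spikes. Its strongest change was a fall of CD44, a hyaluronan receptor (log2 -2.06), where of 12 further probe sets 2 fell and 4 rose. LGALS3, a galectin, rose (log2 0.53), but did not pass with the hybridization spikes (0.16, adjusted p = 0.0674, over a range of 2.14e-06 to 0.0674).

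**Figure D1:**
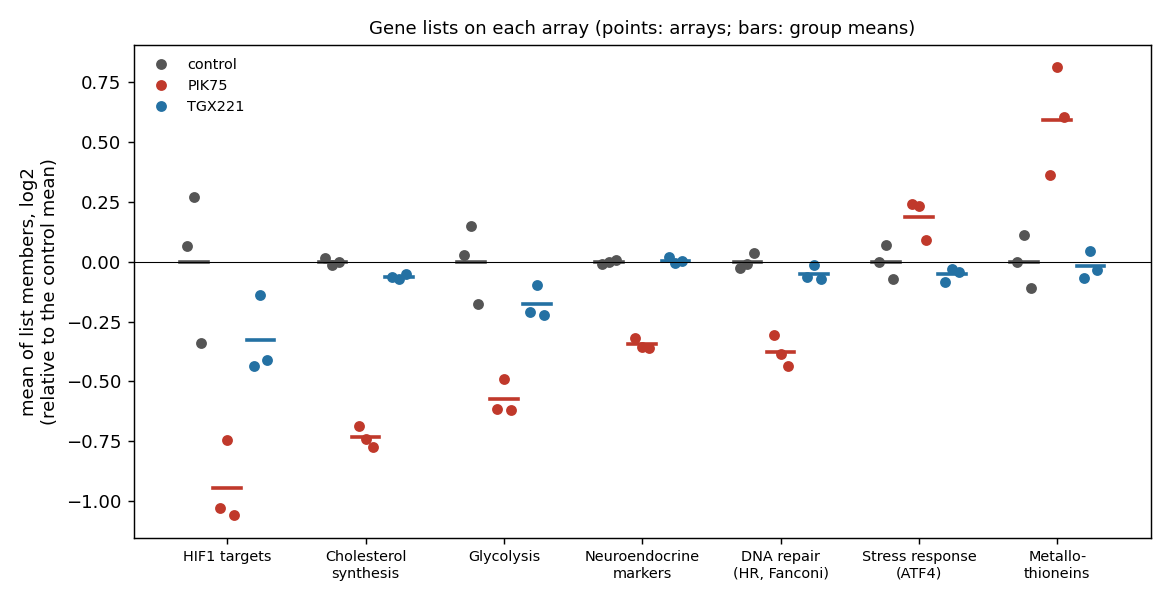
Mean log2 value of the members of 7 gene lists on each array, relative to the control mean of that list. Points are the 3 arrays of a group and bars their mean; HIF1 targets lay at -1.06 to -0.746 with PIK75, at -0.435 to -0.139 with TGX221 and at -0.338 to 0.272 in controls, and the higher values of the ATF4 list with PIK75 (list median 0.25) turned to -0.12 with arrays centred on hybridization spikes.

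Genes of DNA repair and replication were lower as well. In homologous recombination and the Fanconi pathway, 19 of 28 genes fell and 3 rose, against 19 and 4 adjusted over the list alone (median -0.28, adjusted p = 0.000241, and adjusted p = 0.507 with an estimated correlation). RAD51AP1 was 3.54-fold lower (log2 -1.83), BRIP1 lower (log2 -0.999) and MRE11 1.75-fold lower (log2 -0.81, with 1 other probe set higher). DNA replication and the G1/S transition had 25 of 49 genes lower and 10 higher, against 25 and 11 adjusted over the list alone (median -0.15, adjusted p = 0.0105, and adjusted p = 0.638 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, fell (log2 -1.43), as did RFC3 (log2 -1.33), POLE2 (log2 -1.17) and PRIM1 (log2 -1.07), parts of the replication machinery. Mitosis and G2/M was not called (17 of 48 higher, 12 lower, the same counts adjusted over the list alone, adjusted p = 0.982), with CDCA3 higher (log2 1.23) and the spindle motor KIF11 lower (log2 -0.92).

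In oxidative phosphorylation 19 of 36 genes fell and 3 rose, also adjusted over the list alone (median -0.15, adjusted p = 0.0137, and adjusted p = 0.638 with an estimated correlation). UQCRC2 of complex III (log2 -1.21) and NDUFB8 of complex I (log2 -0.83) were among the falls. The mitochondrial ribosome had 20 of 40 genes lower and 8 higher, against 22 and 8 adjusted over the list alone (median -0.16, adjusted p = 0.0137, and adjusted p = 0.683 with an estimated correlation). MRPL39 (log2 -0.78) and MRPL48 (log2 -0.69) were lower and MRPS12 higher (log2 0.88). Chaperones and stress genes of the endoplasmic reticulum had 11 of 25 lower and 3 higher, also adjusted over the list alone (median -0.125, adjusted p = 0.0244, and adjusted p = 0.638 with an estimated correlation). PDIA6 (log2 -0.76) and DNAJB9 (log2 -0.54) fell and HERPUD1 rose (log2 0.62). Target genes of FOXO, transcription factors that PI3K signalling holds in check, had 16 of 33 lower and 8 higher, also adjusted over the list alone (median -0.10, adjusted p = 0.0168, and adjusted p = 0.507 with an estimated correlation). SESN3 (log2 -1.82), the growth arrest genes GADD45A (log2 -1.35) and CCNG2 (log2 -1.23, with 1 other probe set higher), and YPEL2 (log2 -1.30) were among the falls.

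All 7 measured metallothioneins, proteins that bind zinc and copper, rose, and also adjusted over the list alone (median 0.67, adjusted p = 0.0168, and adjusted p = 0.638 with an estimated correlation). MT1H was 1.76-fold higher (log2 0.81), MT1G 1.74-fold (log2 0.80), MT1F 1.61-fold (log2 0.68) and MT2A 1.56-fold (log2 0.64). The integrated stress response under ATF4, which cells use when amino acids run short, had 15 of 29 genes higher and 4 lower, also adjusted over the list alone (median 0.25, adjusted p = 0.0308, and adjusted p = 0.638 with an estimated correlation), but its median was -0.12 once arrays were centred on hybridization spikes. Beside SLC3A2, its partner chain SLC7A5 (log2 0.73) and the pseudokinase TRIB3 (log2 1.41) rose, while DDIT4, also on this list, fell. Histone genes had 14 of 31 higher and 2 lower, against 13 and 2 adjusted over the list alone (median 0.17, adjusted p = 0.0245, and adjusted p = 0.507 with an estimated correlation), with H2BC5 (log2 1.17) and H2AC8 (log2 0.79) among the rises, and the median turned to -0.21 with the hybridization spikes. Of 36 cytoplasmic ribosomal protein genes 15 rose and 0 fell by limma, against 12 and 0 adjusted over the list alone (median 0.0975, adjusted p = 0.0443, and adjusted p = 0.638 with an estimated correlation), where the median was -0.00083 with arrays centred on poly-A spikes and -0.28 with hybridization spikes. RPL32 rose by 0.28 as deposited, but did not pass with the poly-A spikes (0.18, adjusted p = 0.104) or the hybridization spikes (-0.0975, adjusted p = 0.25), over a range of 1.95e-07 to 0.25.

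Within the PI3K pathway itself, 16 of 35 genes fell and 9 rose, against 17 and 9 adjusted over the list alone, and the list was not called (median -0.13, adjusted p = 0.0539). The falls included PIK3R3, a regulatory subunit of PI3K (log2 -1.82, SE 0.0534), PIK3CB (log2 -1.27, SE 0.0572, adjusted p = 4.92e-09), DEPTOR and GSK3B (log2 -1.04, with 1 other probe set higher). PIK3CD, the leukocyte isoform, was higher (log2 0.44), but not past the test with the hybridization spikes (0.07, adjusted p = 0.432, over a range of 3.05e-05 to 0.432). PIK3CG (log2 0.14, adjusted p = 0.141) and the insulin receptor substrate IRS2 (log2 0.11, adjusted p = 0.0866) did not pass as deposited. Both passed higher for the mean of probe sets (0.11, adjusted p = 0.0446, and 0.22, adjusted p = 0.0011) and lower with the hybridization spikes (-0.24, adjusted p = 0.011, and -0.265, adjusted p = 0.00271). IRS2 also passed higher with cyclic loess (0.24, adjusted p = 0.00133), with a trended spread (adjusted p = 0.0496) and without PIK75 replicate 5 (adjusted p = 0.0371), and its second probe set rose (log2 0.32). Over the alternatives the adjusted p ran from 0.0011 to 0.949 for IRS2 and from 0.011 to 0.918 for PIK3CG. In the BCL2 family, 2 of 6 anti-apoptotic genes fell and 3 rose, with the same counts adjusted over the list alone (adjusted p = 0.982). Their median was 0.12 and their mean -0.03, and the median turned to -0.25 with the hybridization spikes. BCL2L2 fell (log2 -0.88) and BCL2L1 was lower (log2 -0.23, adjusted p = 0.014), each with 1 other probe set higher. BCL2L1 did not pass for the mean of probe sets (0.05, adjusted p = 0.474), with cyclic loess (-0.10, adjusted p = 0.328) or without PIK75 replicate 1 (adjusted p = 0.0527), over a range of 1.64e-07 to 0.474. MCL1 did not pass (log2 -0.0039, adjusted p = 0.946), although of its 5 other probe sets 3 fell and 1 rose, and it passed lower for the mean of probe sets (-0.18, adjusted p = 0.0152) and with the hybridization spikes (-0.38, adjusted p = 8.54e-05), over a range of 8.54e-05 to 0.987. The brightest probe set of BCL2 was higher (log2 0.38), while of 3 other probe sets of BCL2, 2 fell and 1 rose. BCL2 passed lower for the mean of probe sets (-0.11, adjusted p = 0.021) and did not pass with the hybridization spikes (0.0097, adjusted p = 0.922), over a range of 0.000142 to 0.922. Of 14 pro-apoptotic members 6 fell and 5 rose, also adjusted over the list alone (median -0.03, adjusted p = 0.536). BNIP3, BNIP3L and BAX (log2 -0.35) were lower, with PMAIP1 higher (log2 0.43). PMAIP1 did not pass with the hybridization spikes (0.06, adjusted p = 0.536, over a range of 1.04e-05 to 0.536). BCL2L11 did not pass as deposited (log2 0.05, adjusted p = 0.368), although 3 of its 6 other probe sets rose (log2 0.45, 0.31 and 0.51). It passed higher for the mean of probe sets (0.22, adjusted p = 0.000555) and with cyclic loess (0.15, adjusted p = 0.0147), and lower with the hybridization spikes (-0.32, adjusted p = 0.000446), over a range of 0.000446 to 0.724. Caspases, death receptors and their inhibitors had 11 of 25 higher and 5 lower, also adjusted over the list alone (adjusted p = 0.798). BIRC5 was higher (log2 0.77) and CASP6 lower (log2 -0.91).

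CDKN1A, a p53 target that encodes p21, fell (log2 -0.84, adjusted p = 2.8e-06), and CDKN1B, which encodes p27, rose (log2 0.54, adjusted p = 0.000189). CDKN1B did not pass with the hybridization spikes (0.17, adjusted p = 0.0911, over a range of 9.26e-06 to 0.0911). CCND1 did not pass (log2 0.11, adjusted p = 0.172) and MYCN was slightly higher (log2 0.16, adjusted p = 0.0185), and both passed lower with the hybridization spikes (-0.26, adjusted p = 0.00399, and -0.22, adjusted p = 0.0123). CCND1 passed higher without control replicate 3 (adjusted p = 0.0151). MYCN did not pass with the poly-A spikes (adjusted p = 0.648), the actin covariate (0.11) or without control replicate 1 (0.0722). The adjusted p ran from 0.00399 to 0.931 for CCND1 and from 0.000384 to 0.648 for MYCN. The list of D cyclins and CDK inhibitors had 6 of 15 members higher and 4 lower, also adjusted over the list alone (adjusted p = 0.798).

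**Figure D2:**
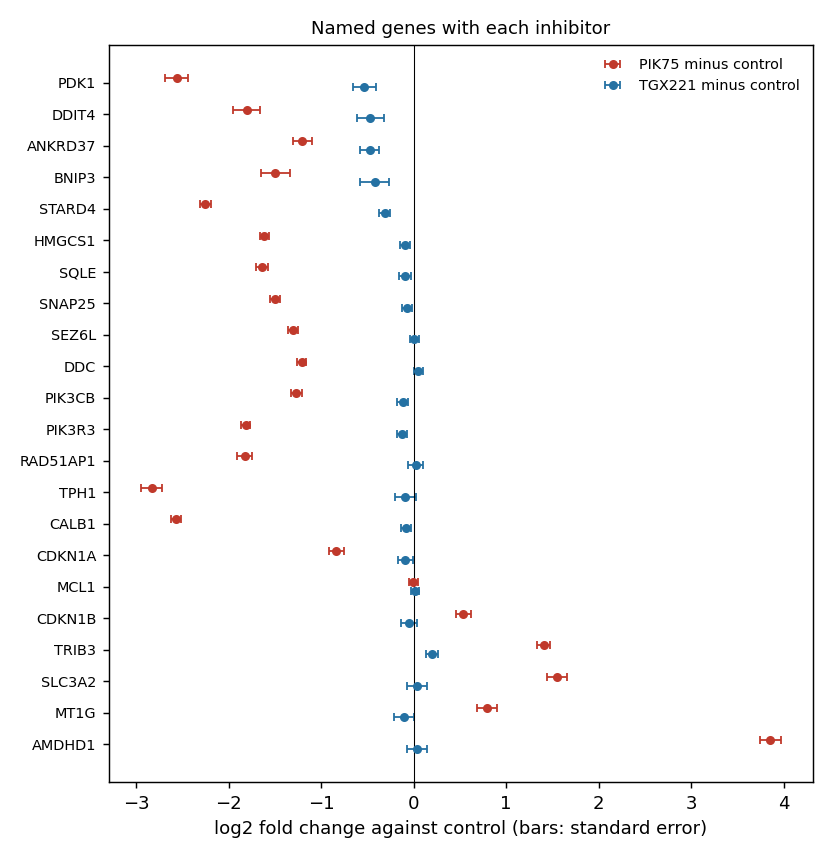
Log2 fold change against control of 22 named genes for PIK75 (red) and TGX221 (blue), with bars for the standard error of the limma fit over 3 arrays per group. PIK75 values ran from -2.83 for TPH1 to 3.86 for AMDHD1, and the TGX221 value of PDK1 was -0.53.

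Across all 19775 genes, limma called 11947 (60.4%) changed with PIK75, 6965 higher and 4982 lower. At 1.5-fold or more the balance turned, with 292 higher and 2062 lower (87.6% lower), and at 2-fold or more 48 were higher and 705 lower. The split of small changes depended on scaling. With arrays centred on the poly-A spikes, 2452 genes were higher and 5475 lower, with cyclic loess 4312 and 5024, and without the dimmer genes 3165 and 4142. The hybridization spikes read 0.37 log2 units higher with PIK75 than with DMSO while the median of the log2 fold changes was 0.09, and relative to the spikes 343 genes were higher and 13816 lower. At 1.5-fold or more the share of falls was 93.4% with poly-A spikes, 82.6% with cyclic loess and 86.2% without PIK75 replicate 5. The actin probe sets of that array showed weaker 5' signal (3' minus 5' value 1.131). The value was 0.4669 and 0.5352 on the other PIK75 arrays, and 0.2394 to 0.4431 on control and TGX221 arrays.

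**Figure D3:**
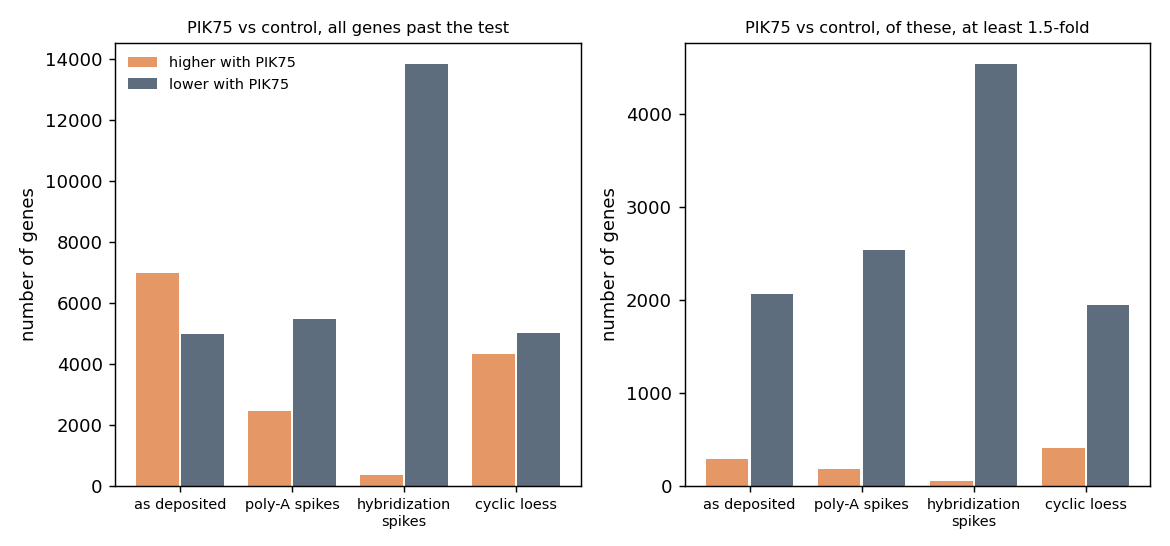
Number of genes higher and lower with PIK75 than with DMSO under 4 array scalings, for all genes past the limma test (left) and those changed at least 1.5-fold (right). As deposited 6965 genes were higher and 4982 lower, and with hybridization spikes 343 and 13816; at 1.5-fold or more falls led under each of the 4 scalings.

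The list calls were unequally firm. Over 20 alternatives that kept the preset correlation, the adjusted p of HIF1 targets stayed between 4.49e-10 and 0.0218, of cholesterol synthesis between 6.33e-09 and 0.00417, of neuroendocrine markers between 5.11e-07 and 0.00891, of glycolysis between 4.06e-06 and 0.0169, of homologous recombination between 0.000153 and 0.0356 and of metallothioneins between 1.42e-06 and 0.025. Without the dimmer genes the calls of DNA replication (adjusted p 0.00485 to 0.655 over the alternatives), oxidative phosphorylation (0.00708 to 0.947), the mitochondrial ribosome (4.95e-05 to 0.909), endoplasmic reticulum chaperones (0.00717 to 0.724), FOXO targets (0.00194 to 0.101) and fatty acid synthesis (0.00318 to 0.108) ended, and cyclic loess ended the first 4 of these 6. Relative to the median of all genes, the median of FOXO targets went from -0.19 to -0.50 without the dimmer genes and that of fatty acid synthesis from -0.40 to -0.43, so these 2 calls ended without a smaller shift. In the other 4 it went from between -0.21 and -0.25 to between -0.07 and -0.11. Poly-A spikes also ended the calls of oxidative phosphorylation, the mitochondrial ribosome and the chaperones, and hybridization spikes those of the mitochondrial ribosome and the chaperones. Such centring moves all genes of an array alike, so the shifts against all genes stayed as deposited (-0.239, -0.246 and -0.213). FOXO targets and histone genes (0.0034 to 0.073) lost their call for the mean of probe sets and ATF4 genes in the fit of 2 groups (7.68e-05 to 0.0507). The call of ribosomal proteins (0.000129 to 0.859) ended without control replicate 1 (adjusted p = 0.0694), control replicate 3 (0.0701), PIK75 replicate 1 (0.0612), TGX221 replicate 2 (0.0507) or TGX221 replicate 5 (0.0505). It also ended with poly-A spikes (0.244), with hybridization spikes (0.859), with the replicate number as a block (0.0748) and in the fit of 2 groups (0.0566). The PI3K pathway list was called without control replicate 5 (0.0467), PIK75 replicate 1 (0.042) or TGX221 replicate 3 (0.0489), over a range of 0.042 to 0.887.

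With TGX221, changes were few and small. GPR160, an orphan receptor, was 1.74-fold lower (log2 -0.80, SE 0.148, adjusted p = 0.0363), and the sodium channel SCN9A and PPP1R3C, a protein that targets a phosphatase to glycogen, were each 1.5-fold lower (log2 -0.59). These 3 were the only genes called at 1.5-fold or more. The largest rise was in PWWP2B (log2 0.56, 1.47-fold, adjusted p = 0.0254). Next came CPEB3, which binds mRNA (log2 0.48), ZSWIM8 (log2 0.47), TMEM151A (log2 0.47) and the ephrin receptor EPHB4 (log2 0.46). Rises of similar size were in the platelet-activating factor receptor PTAFR (log2 0.46), the phosphatase PTPN5 (log2 0.45), TTC9B (log2 0.45) and TMEM92-AS1 (log2 0.445). Other falls were in INTS6 (log2 -0.57), BRWD3 (log2 -0.57), PTH2R (log2 -0.54), ARL6 (log2 -0.485), LNPK (log2 -0.48), ANKRD37 (log2 -0.47) and NID2 (log2 -0.45). These genes were picked among genes whose 3 TGX221 arrays lay apart from the 3 control arrays, as in 4729 genes (23.9%), where chance gives 10%.

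Genes of hypoxia and glycolysis were the lists with the smallest p of camera with TGX221, both lower. Among 22 HIF1 target genes 1 passed over all genes, ANKRD37, against 6 lower and 1 higher adjusted over the list alone, and the median log2 change was -0.38 (adjusted p = 0.000121, and adjusted p = 0.692 with an estimated correlation). In glycolysis and glucose uptake 0 of 23 genes passed over all genes by limma and 7 had an unadjusted p under 0.05, against 0 higher and 6 lower adjusted over the list alone (median -0.14, adjusted p = 0.000361, and adjusted p = 0.692 with an estimated correlation). PDK1 had a value of -0.53 (adjusted p = 0.0576), ALDOC, an aldolase, of -0.65 (adjusted p = 0.0642), DDIT4 of -0.47 (adjusted p = 0.131) and ENO1 of -0.23 (adjusted p = 0.0806). On the arrays, the mean of the HIF1 list was -0.435, -0.139 and -0.412 with TGX221 and 0.0658, 0.272 and -0.338 in controls, so that 1 TGX221 array lay above the lowest control. Chaperones of the endoplasmic reticulum (0 of 25 genes passing by limma, also adjusted over the list alone, and 6 with an unadjusted p under 0.05) were called lower with a median of -0.05, which was 0.02 with the poly-A spikes (adjusted p = 0.0235, and adjusted p = 0.692 with an estimated correlation). So were the subunits of P-TEFb, Mediator and RNA polymerase II (0 of 42 passing by limma, also adjusted over the list alone, and 6 with an unadjusted p under 0.05, median -0.07, adjusted p = 0.0235, and adjusted p = 0.794 with an estimated correlation). Without the dimmer genes or with cyclic loess the calls of both lists ended. Replicate 2 occurs only with TGX221, so the replicate number as a block takes that array out of the comparison. Such a block also ended the calls of both lists (adjusted p = 0.16 for the chaperones and 0.19 for the polymerase list). Poly-A or hybridization spikes ended that of the chaperones too, with the shift against all genes at -0.0474 under both. The call of the chaperones (0.00803 to 0.16 over the alternatives) also ended without control replicate 5 (adjusted p = 0.15) or TGX221 replicate 2 (0.0725). That of the polymerase list (0.0121 to 0.22) ended without control replicate 1 (0.0665) or TGX221 replicate 5 (0.0889).

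Of the small fixed set of PI3K, survival and cell cycle genes, none passed with TGX221 by limma, and BCL2 and BCL2L11 had an unadjusted p under 0.05. PIK3CB, the gene of its target isoform, had a log2 value of -0.12 (SE 0.0572, adjusted p = 0.305) and IRS2 of -0.02. The value was 0.24 for BCL2 (adjusted p = 0.117), which passed with the poly-A spikes (0.31, adjusted p = 0.0369, over a range of 0.0369 to 0.402), 0.01 for MCL1 and -0.14 for BCL2L11 (adjusted p = 0.174). For the cell cycle genes it was -0.09 in CDKN1A, -0.05 in CDKN1B, 0.105 in CCND1 and -0.03 in MYCN. In the PI3K pathway 0 of 35 genes passed over all genes by limma and 10 had an unadjusted p under 0.05, against 2 higher and 1 lower adjusted over the list alone (median -0.03, or 0.04 with the poly-A spikes, adjusted p = 0.296), with PIK3C2B at -0.37 (adjusted p = 0.077). Among 6 anti-apoptotic genes BCL2A1 rose (log2 0.28, adjusted p = 0.0326), against 2 higher adjusted over the list alone, and in autophagy ATG16L1 rose (log2 0.31, adjusted p = 0.0395). Neuroendocrine markers had 0 of 34 genes past the test by limma and 4 with an unadjusted p under 0.05, against 1 higher adjusted over the list alone, and their median was -0.00035 and mean 0.0052, with a median of 0.07 under the poly-A spikes. Cholesterol synthesis and uptake had 1 of 19 genes lower, against 2 adjusted over the list alone (median -0.06, or 0.0069 with the poly-A spikes, adjusted p = 0.119).

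In all, 239 genes (1.21%) were called with TGX221, 160 higher and 79 lower, and 3620 had an unadjusted p under 0.05. With arrays centred on the poly-A spikes the split was 627 higher and 76 lower, and with the hybridization spikes 76 and 608. The count rested on single arrays: it was 4 without control replicate 1, 0 without control replicate 3, 22 without control replicate 5, 61 without PIK75 replicate 3, 0 without TGX221 replicate 2 or TGX221 replicate 5, and 701 without TGX221 replicate 3. None of the 21 genes named above as passing kept its call in every leave-one-out fit.

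PIK75 and TGX221 were compared at these different doses. AMDHD1, dim with TGX221 (mean 5.99), was higher with PIK75 (log2 3.82, SE 0.11, adjusted p = 4.37e-10), ZSCAN16-AS1 5.73-fold higher (log2 2.52) and SLC3A2 2.85-fold higher (log2 1.51). TPH1 was 6.70-fold lower with PIK75 (log2 -2.74), CALB1 5.62-fold (log2 -2.49) and MTURN 5.31-fold (log2 -2.41). DRC8, a dynein regulator of cilia (log2 -2.22), AGR3, a secretory pathway gene (log2 -2.10), and SLC12A2, a chloride cotransporter (log2 -2.07), were also among the 10 largest falls.

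Cholesterol synthesis separated the compounds most clearly by camera, with 15 of 19 genes lower and 1 higher with PIK75 than with TGX221, against 16 and 2 adjusted over the list alone (median -0.62, adjusted p = 1.78e-07, and adjusted p = 0.118 with an estimated correlation). STARD4 differed by -1.94, SQLE by -1.55, HMGCS1 by -1.52 and TM7SF2, a sterol reductase, by -0.96. Neuroendocrine markers followed, with 22 of 34 lower and 2 higher, against 23 and 2 adjusted over the list alone (median -0.29, adjusted p = 6.19e-07, and adjusted p = 0.145 with an estimated correlation). SNAP25 differed by -1.42 and DDC by -1.26. HIF1 targets had 12 of 22 lower and 1 higher, against 13 and 1 adjusted over the list alone (median -0.74, adjusted p = 0.00341, and adjusted p = 0.799 with an estimated correlation), where PDK1 differed by -2.03, HILPDA by -1.35 and DDIT4 by -1.34. Glycolysis had 11 of 23 lower and 0 higher, also adjusted over the list alone (median -0.22, adjusted p = 0.00177, and adjusted p = 0.736 with an estimated correlation).

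Homologous recombination had 17 of 28 genes lower with PIK75 than with TGX221 and 3 higher, also adjusted over the list alone (median -0.28, adjusted p = 0.00107, and adjusted p = 0.463 with an estimated correlation), with RAD51AP1 at -1.85. DNA replication had 24 of 49 lower and 11 higher, against 25 and 11 adjusted over the list alone (median -0.15, adjusted p = 0.0192, and adjusted p = 0.839 with an estimated correlation), with RRM2 at -1.46. Oxidative phosphorylation had 20 of 36 lower and 3 higher, against 21 and 3 adjusted over the list alone (median -0.175, adjusted p = 0.00135, and adjusted p = 0.736 with an estimated correlation), with UQCRC2 at -1.22. The mitochondrial ribosome had 17 of 40 lower and 10 higher, also adjusted over the list alone (median -0.11, adjusted p = 0.0281, and adjusted p = 0.859 with an estimated correlation), with MRPL48 at -0.69 and MRPS12 at 0.84. Fatty acid synthesis had 9 of 14 lower and 1 higher, also adjusted over the list alone (median -0.17, adjusted p = 0.0069, and adjusted p = 0.199 with an estimated correlation), with ACACA at -0.73. FOXO targets had 14 of 33 lower and 6 higher, against 15 and 7 adjusted over the list alone (median -0.13, adjusted p = 0.0182, and adjusted p = 0.463 with an estimated correlation), with SESN3 at -1.57 and GADD45A at -1.34. Targets of NRF2, the regulator of oxidative stress genes, were called in this comparison, 9 of 19 lower and 2 higher, also adjusted over the list alone (median -0.23, adjusted p = 0.0281, and adjusted p = 0.408 with an estimated correlation). Glutathione reductase GSR (log2 -1.05), PGD of the pentose phosphate pathway (log2 -1.09, with 2 other probe sets higher) and NQO1 (log2 -0.81) were lower and MAFG higher (log2 0.70).

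Metallothioneins had 6 of 7 genes higher with PIK75 than with TGX221, also adjusted over the list alone (median 0.70, adjusted p = 0.0132, and adjusted p = 0.739 with an estimated correlation), with MT1H 2.00-fold and MT1G 1.86-fold higher. Histone genes had 16 of 31 higher and 1 lower, against 17 and 1 adjusted over the list alone (median 0.21, adjusted p = 0.00437, and adjusted p = 0.384 with an estimated correlation), with H2BC5 at 1.27, and the median turned to -0.10 with the hybridization spikes. The ATF4 list had 16 of 29 higher and 3 lower, against 16 and 4 adjusted over the list alone (median 0.29, adjusted p = 0.00827, and adjusted p = 0.684 with an estimated correlation), with TRIB3 at 1.21, and its median was -0.02 with the hybridization spikes. PIK3R3 (log2 -1.69), PIK3CB (log2 -1.15, adjusted p = 1.23e-08) and CDKN1A (log2 -0.75) were lower with PIK75 than with TGX221, and CDKN1B was higher (log2 0.59). As deposited MCL1 (-0.02, with a 95% interval from -0.12 to 0.08), BCL2 (0.14, from -0.02 to 0.30) and IRS2 (0.13, from 0.02 to 0.24, adjusted p = 0.0527) did not pass. These 3 depended on the processing. MCL1 passed with hybridization spikes (-0.32, adjusted p = 0.00062), and BCL2 passed lower for the mean of probe sets (-0.28, adjusted p = 8.42e-05) and higher with cyclic loess (0.23, adjusted p = 0.0287). IRS2 passed higher without PIK75 replicate 5 (0.17, adjusted p = 0.0236), and also with median centring, array weights, the dimmer genes out, a trended spread, cyclic loess, the actin covariate and the mean of probe sets (0.24, adjusted p = 0.000709), but lower with hybridization spikes (-0.17, adjusted p = 0.0421). Their adjusted p ran from 0.00062 to 0.995 for MCL1, 8.42e-05 to 0.876 for BCL2 and 0.000709 to 0.815 for IRS2.

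Between the inhibitors 9379 genes (47.4%) differed by limma, 4967 higher and 4412 lower with PIK75, and at 1.5-fold or more 343 were higher and 1669 lower. The hybridization spikes were 0.31 log2 units higher with PIK75 than with TGX221 and the poly-A spikes 0.16, while the median of the log2 fold changes was 0.06. Relative to the hybridization spikes 568 genes were higher and 12657 lower, relative to the poly-A spikes 1022 and 6043, and without the dimmer genes 2605 were higher and 3815 lower. The calls of HIF1 targets, glycolysis, homologous recombination, DNA replication, oxidative phosphorylation, the mitochondrial ribosome, fatty acid synthesis, FOXO targets and NRF2 targets ended without the dimmer genes. Relative to the median of all genes, the median of HIF1 targets then went from -0.80 to -0.73, of glycolysis from -0.29 to -0.25, of homologous recombination from -0.34 to -0.28, of NRF2 targets from -0.29 to -0.23 and of FOXO targets from -0.20 to -0.425. Larger losses were in DNA replication (-0.21 to -0.12), oxidative phosphorylation (-0.24 to -0.15), fatty acid synthesis (-0.23 to -0.14) and the mitochondrial ribosome (-0.18 to -0.09). Cyclic loess ended those of glycolysis, DNA replication, oxidative phosphorylation, the mitochondrial ribosome and NRF2 targets. Hybridization spikes ended those of DNA replication (adjusted p = 0.095, over a range of 0.0113 to 0.824), the mitochondrial ribosome (0.208) and NRF2 targets (0.095, over a range of 0.0202 to 0.348). Their shifts against all genes stayed as deposited under that centring. The actin covariate ended those of the mitochondrial ribosome (0.0902) and NRF2 targets (0.0646), poly-A spikes that of the mitochondrial ribosome (0.162), and the mean of probe sets those of FOXO targets (0.10, over a range of 0.00521 to 0.138) and NRF2 targets (0.0856). The call of the mitochondrial ribosome also ended without PIK75 replicate 3 (adjusted p = 0.0801) or TGX221 replicate 2 (0.0638), over a range of 0.000115 to 0.887.

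Of the 239 genes called with TGX221, 228 were also called with PIK75, 155 higher with both, 61 lower with both and 12 in opposite directions. This count rested on single arrays: it was 4 without control replicate 1, 22 without control replicate 5, 55 without PIK75 replicate 3, 646 without TGX221 replicate 3, and 0 without control replicate 3, TGX221 replicate 2 or TGX221 replicate 5. It was also 0 in the fit of 2 groups. Independent lists of these sizes would share 144.4 genes, 56.35 of them higher with both and 19.9 lower with both. Simulated unchanged groups against the same 3 controls shared 0.02 on average and 2 at most. The simulations held no change with either inhibitor. They cannot show what shared controls add when 60.4% of genes are called with PIK75. Both comparisons use the same controls, which are too few to be split, so part of the excess may come from them. Across genes the log2 fold changes of the inhibitors correlated at r = 0.481, with the same sign in 68.5% of genes. The simulations gave a mean r of 0.50 (0.4813 to 0.5172) and the same sign in 66.7%, set by noise and shared controls alone. These 2 values are no reference for the real data, where fold changes spread far more with PIK75 (SD 0.4138) than with TGX221 (SD 0.1177). The covariance was 0.0234, which is 0.021 above the 0.0024 that noise and shared controls gave in the simulations. The simulations drew each gene independently, so errors shared by the genes of an array are missing from them. How much of the covariance comes from the shared controls therefore stays unknown. ANKRD37 was the 1 HIF1 target called lower with both inhibitors.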

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

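All 4 items below were measured after the arrays had been read and concern signals outside the tests of genes. The hybridization spikes, which are added in equal amounts after labelling, were higher by 0.3729 log2 units on the PIK75 arrays than on the control arrays. Their offsets ran from 0.206 to 0.260 on PIK75 arrays and from -0.190 to -0.0904 on control arrays. The cause of this shift was not tested. PIK75 replicate 5 had an actin 3' minus 5' value of 1.131. The other PIK75 arrays had 0.4669 and 0.5352, and the control and TGX221 arrays 0.2394 to 0.4431. Its dap spike 3' minus 5' value was 1.946, against 1.035 to 1.215 on the other 8 arrays. The dap spike is added to the RNA before labelling, so the weaker 5' signal on PIK75 replicate 5 is also present in a transcript that the cells did not make.

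Of the 11721 probe sets without a gene symbol, 120 changed at least 2-fold with PIK75, 26 higher and 94 lower. With TGX221 the count was 0 by limma at 2-fold, with 28 of these probe sets called at any fold. Between the inhibitors 98 differed at least 2-fold. Which transcripts these probe sets measure was not examined.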

How the results depend on the processing

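Hybridization spikes, cyclic loess and the actin covariate were chosen after seeing the data; the cause of a changed result was not tested. Leaving out genes below the median brightness reduced the number of genes tested. Testing every probe set raised the number of tests above that of genes. Counts under these settings therefore do not show whether the share of changed genes or probe sets fell or rose. The count of genes changed with PIK75 was 7927 with poly-A spikes, 7307 without dim genes, 27400 for every probe set, 2354 at 1.5-fold, and 10242 to 11910 when 1 array was left out. With TGX221 it was 703 with poly-A spikes, 30 for the mean of probe sets, 147 for every probe set, 0 by limma in the fit of 2 groups, 1313 with array weights, 0 with the replicate block, 3 at 1.5-fold, 0 at the stricter threshold, 684 with hybridization spikes, 144 with the actin covariate, and 0 to 701 when 1 array was left out. Between the inhibitors it was 20304 for every probe set, 2012 at 1.5-fold, and 7752 to 9243 when 1 array was left out. The genes called in both numbered 431 with poly-A spikes, 29 for the mean of probe sets, 139 for every probe set, 0 in the fit of 2 groups, 1157 with array weights, 0 with the replicate block, 3 at 1.5-fold, 0 at the stricter threshold, 584 with hybridization spikes, 121 with the actin covariate, and 0 to 646 when 1 array was left out.

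Lists called fell to 9 without dim genes with PIK75 and to 6 between the inhibitors, and to 0 with an estimated correlation in all 3 comparisons. With TGX221, 7 lists were called with a trended and robust spread and 2 with the replicate block. That block gave 11424 genes with PIK75 and 7771 between the inhibitors. Replicate 2 occurs only with TGX221, so the block also takes that array out of the comparisons. Deviations of arrays with the same number correlated at -0.134 to 0.235, and those of arrays with different numbers at -0.292 to 0.256. The numbers thus gave no sign of pairing, but 3 arrays per group are too few to exclude it.

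Of 92 genes named as passing with PIK75, 80 passed under all alternatives and 90 in every leave-one-out fit; all 38 did between the inhibitors. Signs turned for the mean of probe sets in NUP58 (-0.0285), BCL2 (-0.114; between the inhibitors -0.284) and BCL2L1 (0.0458), and with hybridization spikes in RPL32 (-0.0975), PIK3CG (-0.236), IRS2 (-0.265; between the inhibitors -0.174), BCL2L11 (-0.321), CCND1 (-0.262) and MYCN (-0.216). BCL2L1 did not pass without PIK75 replicate 1 (adjusted p = 0.0527) nor MYCN without control replicate 1 (0.0722), while CCND1 passed without control replicate 3 (0.0151) and IRS2 without PIK75 replicate 5 (0.0371).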

Other observations

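The tests chosen after the result was seen are those on the falls of 1.5-fold or more, those on HIF1 targets and that on dim probe sets, and the hybridization spikes and cyclic loess as scalings. The lists described next were not called with PIK75. Of all 19775 genes 6965 were higher and 4982 lower (60.4% changed). The shares of changed members lay near that in autophagy, short-lived transcripts, receptor tyrosine kinases and the polymerase list. They were larger in p53 targets, NRF2 targets, splicing regulators and fibroblast markers, and smaller in leukocyte and endothelial markers. Among genes of autophagy, 12 of 37 rose and 10 fell (median 0.07, mean -0.02, adjusted p = 0.982, with a median of -0.03 under poly-A spikes), with the protease ATG4A lower (log2 -1.11) and ATG101, part of the initiating kinase complex, higher (log2 0.53, or 0.16 with the hybridization spikes, adjusted p = 0.0838, over a range of 5.46e-07 to 0.0838). Immediate early and other short-lived transcripts had 15 of 43 higher and 11 lower (median 0.05, mean -0.02, adjusted p = 0.932, with a median of -0.05 under poly-A spikes). JUND (log2 -1.22, with 1 other probe set higher) and TOB1, an antiproliferative gene (log2 -1.11), were lower and the phosphatase DUSP6 was higher (log2 0.56). Receptor tyrosine kinases and adaptors had 10 of 28 higher and 7 lower (median 0.09, mean -0.04, adjusted p = 0.982, with a median of -0.28 under hybridization spikes), and KIT, a receptor often present in this tumour type, fell (log2 -0.70).

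Target genes of p53 had 6 of 21 members higher and 11 lower with PIK75 and were not called (median -0.23, adjusted p = 0.0539), but passed with the poly-A spikes (adjusted p = 0.0334) and without control replicate 3 (0.0488), PIK75 replicate 1 (0.042) or TGX221 replicate 3 (0.0489), over a range of 0.0334 to 0.695. The polymerase and Mediator list had 10 of 42 higher and 17 lower (median -0.07, adjusted p = 0.113) and passed without PIK75 replicate 1 (0.042), over a range of 0.042 to 0.947. Target genes of NRF2 had 5 of 19 higher and 9 lower (median -0.27, adjusted p = 0.124). Splicing regulators had 11 of 33 higher and 12 lower (median 0.02, mean -0.08, adjusted p = 0.535, with a median of -0.08 under poly-A spikes), and were called lower for the mean of probe sets (adjusted p = 0.015, over a range of 0.015 to 0.983, and 0.011 against TGX221). Adjusted over the list alone, the counts of these lists were the same, except for splicing regulators (12 and 13). Lists of lysosome genes, ribosome biogenesis, MYC targets (adjusted p = 0.276 with PIK75), tRNA synthetases, heat shock proteins, the proteasome, interferon, NF-kB, Notch (0.288) and Wnt were not called as deposited in any of the 3 comparisons. With cyclic loess, tRNA synthetases (0.0295) and mitosis genes (0.0265) were called higher with PIK75, and proteasome subunits with TGX221 (0.0427). Proteasome subunits were also called higher with TGX221 without the dimmer genes (0.0323) and with a trended spread (0.047). For the mean of probe sets they were called lower with PIK75 than with TGX221 (0.0498).

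The 3 lists of markers of cells other than the tumour line were not called with PIK75. Of 12 fibroblast genes 9 rose and 1 fell (median 0.24, or -0.13 under hybridization spikes, adjusted p = 0.124), with COL1A2 higher (log2 0.40, or 0.03 with these spikes, adjusted p = 0.781, over a range of 4.95e-05 to 0.781) and POSTN lower (log2 -0.86). Of 12 leukocyte genes 6 rose and 0 fell by limma (median 0.15, or -0.23, adjusted p = 0.188), ITGAM among them (log2 0.38, or 0.01 with these spikes, adjusted p = 0.919, over a range of 0.000359 to 0.919). Of 9 endothelial genes 4 rose, or 5 adjusted over the list alone, and 1, CLDN5 (log2 -0.80), fell (median 0.17, or -0.20, adjusted p = 0.62). With TGX221, oxidative phosphorylation was not called (median 0.04, or -0.02 under hybridization spikes, adjusted p = 0.0931) but passed without the dimmer genes (0.00673), with a trended spread (0.00691), with cyclic loess (0.0317) and without TGX221 replicate 5 (0.048), over a range of 0.00673 to 0.446.

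Groups of 3 arrays can be split in 10 ways, too few for a share under 0.05. The real PIK75 split gave 11947 genes and the other splits 0 at most, so that 1 split reached the real count. Every other split mixes arrays of both groups, so a large difference between the groups enters the spread and lowers the count of genes. The low gene counts of the other splits therefore cannot judge chance. For PIK75 lists the real split gave 15 and the others at most 11, for TGX221 genes 239 and at most 1, for TGX221 lists 4 and at most 6 (5 splits reached the real count), and between the inhibitors 9379 genes against 0 and 14 lists against 13. For the genes called in both, 2 of 100 assignments of the 9 arrays to 3 groups reached 228. The highest other count, 8125, came from taking the 3 PIK75 arrays as the control group. Assignments that mix PIK75 arrays with others put the PIK75 effect into the spread, and the median of the other counts was 0. The share of 2 in 100 therefore cannot measure chance in the overlap.

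Most PIK75 changes of 1.5-fold or more were falls (87.6%). RNA quality of PIK75 replicate 5 was excluded as the sole source, since 86.2% were falls without it. The actin 3' minus 5' values of the other PIK75 arrays (0.4669 and 0.5352) also lay above those of control and TGX221 arrays (0.2394 to 0.4431). A weaker 5' signal shared by the PIK75 arrays was therefore not excluded. With the actin value as a covariate 84.5% of the 1.5-fold changes were falls. The GAPDH 3' minus 5' values overlapped between groups. They were -0.00206 to 0.07812 with PIK75, -0.05188 to 0.01313 in controls and 0.002684 to 0.01822 with TGX221. Falls were more frequent among bright genes: the median change was 0.112, 0.16, 0.0544 and -0.141 in 4 groups of genes of equal size, from the dimmest to the brightest. Cyclic loess, which removes such a trend, left 82.6% of the changes as falls, so the trend was not the whole source and stays open as a part of it. For a general transcription block, which would lower short-lived transcripts, a bound of -0.585 was set after the values were seen. Their median was 0.0509 as deposited and -0.322 with arrays centred on hybridization spikes, short of that bound. The bound is arbitrary and a common change cannot be measured from these values, so a transcription block stays open. A change common to most genes stays open as well.

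HIF1 target genes were called lower with PIK75 and with TGX221 at the preset correlation, but not with an estimated correlation (adjusted p = 0.638 and 0.692), and with TGX221 1 of 22 members passed. Differences between cultures stay open for both: the highest PIK75 array mean lay -0.408 from the lowest control, against a range of 0.61 among controls, and for TGX221 the same value was 0.199. Without PIK75 replicate 5 the median was -1.06, so RNA quality of that array was excluded as the sole source. A weaker 5' signal shared by the PIK75 arrays is not covered by that fit. An effect of the inhibitors and a difference between cultures, such as in cell density or oxygen, cannot be told apart here.

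With PIK75, 982 of the 10523 genes with more than 1 probe set had 2 or more of them changed by at least 1.5-fold. Among these 982 genes, 56 (5.70%) had probe sets that moved in opposite directions by at least 1.5-fold. The pattern held for 27 genes with bright probe sets only, for 49 without PIK75 replicate 5, and for 29 with probe sets of single-transcript design. Leaving out that array does not cover a weaker 5' signal shared by the PIK75 arrays. Examples chosen after seeing the values are the splicing factor SRSF1 (log2 -0.60 and 1.23) and the RNA-binding protein HNRNPD (log2 -1.33 and 0.85). In both genes every other probe set changed by at least 1.5-fold fell. Altered isoforms or polyadenylation sites could give this pattern, as could a wrong gene assignment of a probe set, and neither was tested, since probe positions were not used here.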
